A study of Danio rerio with 16 samples.

How the data were processed

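RNA sequencing measured transcripts in larvae of the zebrafish (Danio rerio) that were 7 days old and had been exposed for 7 days to perfluorobutanoic acid (PFBA), a short-chain perfluorinated acid. Per the labels, the 16 samples formed 4 groups: a control given the solvent dimethyl sulfoxide (n = 4), and PFBA at 0.1 µg/L (n = 3), 1 µg/L (n = 4) and 10 µg/L (n = 5). Per the labels' protocols, larvae were flash frozen, total RNA was extracted with TRIzol, polyadenylated RNA was selected, and strand-specific libraries were made with dUTP and sequenced on an Illumina instrument.

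The authors deposited 3 tables, 1 for each dose, and each repeated the same control columns. Each table held raw counts of reads per gene and library, which the authors had not normalized. The submitters' processing notes name fastp, HISAT2, featureCounts and DESeq2 and the genome build GRCz11, without versions or order. The strand setting of the counting and the annotation release are not given in the sources used here, so genes that overlap another gene, or that share reads with a near-identical paralog such as the crystallins, opsins and myosins, have less certain counts. The deposited tables also held the authors' log2 fold change of exposed over control samples for each gene. A p-value and an adjusted p-value per gene, as deposited, came from the authors' own test. An adjusted p of 1 in the authors' tables also stood for genes that had a small unadjusted p: 11 genes at 0.1 µg/L and 2 genes at 1 µg/L had an unadjusted p below 0.0001 beside it. The authors' own normalized columns were not used here.

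The tables listed 24975, 25272 and 25531 genes at 0.1, 1 and 10 µg/L, each with at least 2 reads over its libraries. They were joined by gene identifier into 26183 genes, 24560 of them in all 3 tables. A gene missing from a table was given a count of 0 in that table's exposed libraries, which filled 10528 cells, and such genes had at most 1 read over the control libraries. No column of per-sample values was left unmatched. The numbers in the names of the control and 1 µg/L columns differ from those in the sample titles, so those columns were assigned to their group but not to a titled sample. Libraries are named here by the number in the deposited column name. No pair of libraries was a duplicate: the closest pair, library 1 at 10 µg/L and library 1 at 1 µg/L, had a Pearson correlation across genes of 0.9751 and a chi-square of 9.02 per degree of freedom.

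Genes were filtered with filterByExpr, which left 19092 genes, and scaled with trimmed mean of M values (TMM) factors. Each comparison was tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust fit) in 1 fit of all 16 libraries with 12 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p below 0.05. Each dose was compared with control, the doses were compared with each other, an F test covered the 4 groups, and a dose trend was fitted as a slope over equal steps from control through 0.1 and 1 to 10 µg/L. Levels are CPM, the usual scaling of counts to a common library size, with TMM-scaled library sizes, as mean ± SD over libraries, and log2 CPM used a prior count of 2. The standard error (SE) of a log2 fold change was derived from the F statistic.

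A total of 44 gene lists covering pathways, organs and cell types, with 1172 symbols, was fixed before the data were examined, as were the design, the rule for named genes and the alternatives, apart from those named below as added. Of these symbols 1101 were matched to an identifier, 1095 by the gene name in the tables and 6 by a reference symbol. Lists with at least 5 measured members were tested with limma's camera (limma 3.58.1) on voom values with a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists. The camera test was repeated with a correlation estimated per list and fry was run as another test. With an estimated correlation, 0 of the lists called with the preset value kept their call in any comparison. Counts of members "adjusted over the list alone" used the same edgeR p-values adjusted within each list.

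Genes were named by a rule that took, for each dose, up to 10 called genes with the largest rise and up to 10 with the largest fall. Placeholder names and genes with a mean under 2 CPM were left out. Where fewer than 5 genes passed, the 5 with the lowest p were given as values. The rule added up to 4 members with the lowest p of each called list, genes called at more than 1 dose, up to 5 genes in each direction of the dose trend, and the genes pparaa, pparab, pparg, cpt1aa, fabp1a, cyp1a, cat, sod1 and hmox1a. Some genes that the rule takes are not reported here. pparg did not pass the filter and fabp1a was not matched to an identifier, so both were not analysed here. The rule's pattern for clone names covered shorter numbers than those of CABZ01051602.1 and CABZ01078055.1, which it therefore kept, and the dose trend part had no limit on names or levels.

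The edgeR step was tested on simulated counts for these 19092 genes with known changes. The changed genes were drawn from the more abundant ones, with 66 or 67 genes per fold change, so recovery among genes with few reads was not tested. At 10 µg/L it recovered 80.3% of genes changed 4-fold, 23.9% of those changed 2-fold and 0% of those changed 1.5-fold. At 1 µg/L the shares were 78.8%, 22.4% and 1.5%, and at 0.1 µg/L they were 75.8%, 10.4% and 1.5%. At most 1 unchanged gene was called in each comparison. In the list step, a simulated 1.5-fold shift of the circadian clock list was called, with 1 other list.

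Alternatives were DESeq2 size factors in edgeR, library size without scaling, no filter on low counts, DESeq2 1.42.0, limma-voom with quality weights, fits of only the groups compared, a trend over the exposed groups alone, controls split into pairs, and leaving out each of the 16 libraries in turn. Alternatives added after seeing the data were a block for the number in the column name, fits without libraries 1 and 2 at 0.1 µg/L, fits without these and library 5 at 1 µg/L, removal of a gene-length trend per library, and the effect of each alternative on the overlap between doses. A block for the number in the sample titles was not run, because the control and 1 µg/L columns do not carry those numbers. Total counts per library were between 9708464 and 13862232. Nothing in the labels says whether samples came from separate clutches or tanks, or how many larvae each held, so p-values measure the spread between these samples. Collection times and library batches are not given in the sources used here.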

Results

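Transcript levels were measured by RNA sequencing in zebrafish larvae given solvent or PFBA at 0.1, 1 or 10 µg/L, with 16 libraries in all. Total counts were 11570175, 12901377, 13735339 and 11353254 reads in control libraries 1, 3, 4 and 5. At 0.1 µg/L libraries 1, 2 and 3 held 13862232, 13005032 and 10678812 reads. At 1 µg/L libraries 1, 2, 4 and 5 held 11925763, 10503631, 12461311 and 12069555 reads. At 10 µg/L libraries 1 to 5 held 12424856, 11374453, 9708464, 11979207 and 13089123 reads. Of all genes, 19092 had enough reads to be tested.

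Libraries 1 and 2 at 0.1 µg/L stood apart from the rest. They lay at 174.7 and 101.2 on the first principal component of log2 CPM, which held 38.9% of the variance, while all others lay between -43.8 and 9. Their TMM factors were 0.58 and 0.74, against 0.93 to 1.14 in all others. Their 10 most abundant genes took 17.05% and 14.43% of the reads, against 9.46% to 11.89% elsewhere, and 20118 and 21183 genes had a read, against 21247 to 22975 elsewhere. Library 3 at 10 µg/L lay lowest on the second component, at -99.6, followed by control library 5 at -54.

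**Figure D1:**
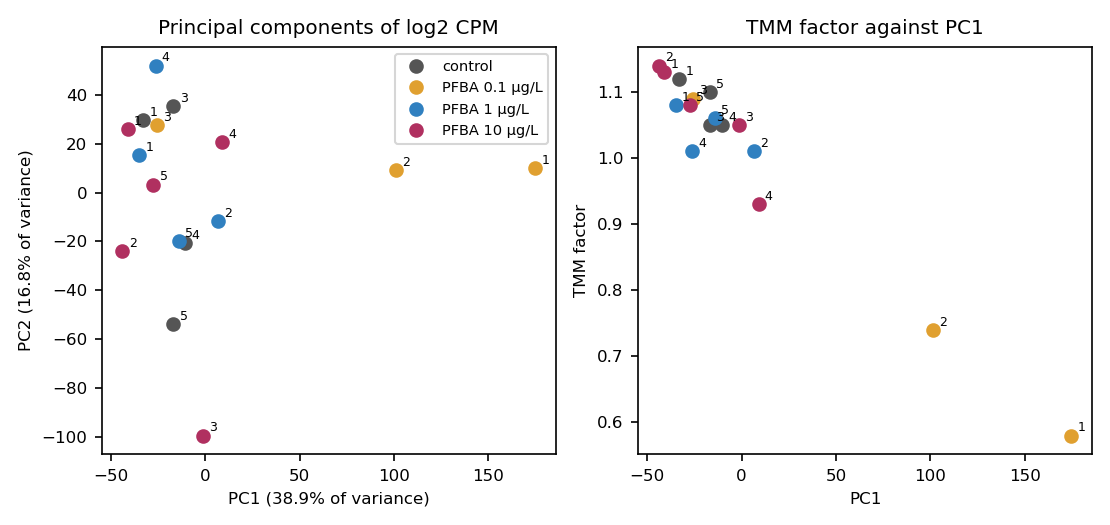
Left, the first 2 principal components of log2 CPM for the 16 libraries, coloured by group and marked with the library number; right, the TMM scaling factor against the first component. Libraries 1 and 2 at 0.1 µg/L lie at 174.7 and 101.2 on the first component with TMM factors of 0.58 and 0.74.

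The comparison of 10 µg/L with control asked which transcripts differ after exposure to the highest dose, and of 29 measured genes of the fixed circadian clock list 3 rose and 5 fell. nr1d1, which encodes the clock repressor Rev-erb alpha, fell from 660 ± 108 CPM in controls (SD, n = 4) to 39.9 ± 9.59 CPM (SD, n = 5), a 16.5-fold lower level (edgeR adjusted p = 0.0493). ciarta, another repressor of the clock, fell 8.01-fold (log2 fold change -3.00, SE 0.54, edgeR adjusted p = 0.0226). bhlhe41, a repressor of clock-driven transcription, fell 5.88-fold, and dbpb, a clock output factor of the PAR bZIP family, fell 5.60-fold. arntl1a, which encodes the activator Bmal1, rose from 33.6 ± 6.49 to 78.9 ± 12.9 CPM (SD, n = 4 and 5), with an edgeR adjusted p of 0.0112. The repressor gene nfil3-5 rose 3.49-fold, and aanat2, which encodes the rate-limiting enzyme of pineal melatonin synthesis, rose 3.17-fold. Outside the fixed clock list, the cryptochrome gene cry3b rose 5.71-fold and the nuclear receptor gene rorcb 5.54-fold.

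Of the 35 measured genes of the fixed photoreceptor list 2 passed at the same dose (adjusted p of the list = 0.496 with an estimated correlation, limma camera). gngt2a, a cone transducin gamma subunit, rose 2.78-fold, and the green cone opsin gene opn1mw1 rose from 1020 ± 235 to 2190 ± 521 CPM (SD, n = 4 and 5; edgeR adjusted p = 0.0396). Outside that list, guca1e, which encodes a guanylate cyclase activator, rose 7.66-fold, from 15.0 ± 2.97 to 115 ± 49.1 CPM (SD, n = 4 and 5; edgeR adjusted p = 0.000936). neurod1, a transcription factor of neurons and photoreceptors, rose 2.49-fold, ptpdc1b rose 2.39-fold and fbxl3l rose 5.28-fold. nr4a1, an orphan nuclear receptor gene, fell 6.34-fold (log2 fold change -2.66, SE 0.31, edgeR adjusted p = 0.000936), and the AP-1 genes fosl1a and fosab fell 6.07-fold and 2.97-fold. hsp90aa1.2, which encodes a cytosolic Hsp90 chaperone, fell from 166 ± 22.1 to 51.7 ± 8.28 CPM (SD, n = 4 and 5; edgeR adjusted p = 0.000936). nmrk2, a nicotinamide riboside kinase gene, fell 5.90-fold, itpkcb, an inositol trisphosphate kinase gene, fell 3.33-fold, gpr186 fell 3.49-fold, and CABZ01051602.1 fell 5.40-fold. In each of the genes named as changed at this dose all 5 exposed libraries lay on the same side of the control mean, which the choice of genes by their p-value favours.

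In GRCz11, nr1d1 (ENSDARG00000033160) lies on chromosome 3 from 23488652 to 23496223, ciarta (ENSDARG00000058094) on chromosome 19 from 8928434 to 8940068, and arntl1a (ENSDARG00000006791) on chromosome 25 from 17893784 to 17918810. cry3b (ENSDARG00000091131) lies on chromosome 22 from 786556 to 809282 and guca1e (ENSDARG00000101567) on the same chromosome from 1092479 to 1109547. nr4a1 (ENSDARG00000000796) lies on chromosome 23 from 32149269 to 32194397, hsp90aa1.2 (ENSDARG00000024746) on chromosome 20 from 53967350 to 53981626, per2 (ENSDARG00000034503) on chromosome 2 from 48309600 to 48375342 and egr4 (ENSDARG00000077799) on chromosome 23 from 45579497 to 45581626. The counts cover whole genes and do not separate exons.

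In all, 43 genes passed at 10 µg/L, 16 higher and 27 lower (edgeR, Benjamini-Hochberg), of 1572 at an unadjusted p below 0.05. A fit of these 2 groups alone called 157 genes, 41 higher and 116 lower, including all 43, DESeq2 called 259 and limma-voom 323. In the authors' deposited table the adjusted p was below 0.05 in 390 genes, 154 higher and 236 lower. The count was 15, 10, 14 and 28 without control library 1, 3, 4 or 5, and 14, 27 and 23 without library 2, 4 or 5 at 10 µg/L, with more higher than lower genes without library 2 (8 and 6) or 4 (14 and 13). It was 93 without library 3 at 0.1 µg/L, 131 without library 5 at 1 µg/L, and 80 without libraries 1 and 2 at 0.1 µg/L. guca1e, nr4a1, nmrk2, itpkcb and hsp90aa1.2 kept their call in all 26 alternatives and cry3b in every fit with 1 library left out.

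Leaving out 1 library ended other calls at 10 µg/L, with edgeR adjusted p-values given here. bhlhe41 lost its call without control library 4 (0.0509) or library 2 at 10 µg/L (0.0536), aanat2 without control library 1 (0.0624) or 3 (0.0579), and CABZ01051602.1 without control library 3 (0.0574) or library 2 at 10 µg/L (0.0527). arntl1a, neurod1 and rorcb lost it without control library 1 (0.0577, 0.0712 and 0.0734), 3 (0.0574, 0.0579 and 0.0707) or 4 (0.054, 0.054 and 0.0709). fosab lost it without control library 3 (0.054), 4 (0.0692) or 5 (0.0566) or library 2 at 10 µg/L (0.0677). Of the 16 such fits, nr1d1 lost its call in 12, nfil3-5 in 11, ciarta, fbxl3l and opn1mw1 in 10 each, gpr186 in 9, dbpb in 8, fosl1a in 7, gngt2a in 5 and ptpdc1b in 4. Their highest values were 0.159 for nfil3-5, fbxl3l and opn1mw1, 0.107 for fosl1a, 0.0785 for gngt2a and 0.0761 for ptpdc1b without control library 1, 0.151 for nr1d1 and gpr186 without library 2 at 10 µg/L, and 0.0881 for ciarta and 0.082 for dbpb without library 4 at 10 µg/L. Library size only ended the calls of nr1d1 (0.0749), nfil3-5 (0.171), fbxl3l (0.0887), opn1mw1 (0.111), gpr186 (0.142) and ptpdc1b (0.0948), and no filter on low counts those of nr1d1 (0.0996), ciarta (0.0663) and gpr186 (0.0596). Without libraries 1 and 2 at 0.1 µg/L the calls of nr1d1 (0.105), ciarta (0.0745) and dbpb (0.0543) ended. Of the 16 fits nr1d1 kept its call only in those without a library at 1 µg/L, and in the edgeR fit of the compared groups alone it had an adjusted p of 1.6e-06 (range over its alternatives 1.68e-08 to 0.151).

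**Figure D2:**
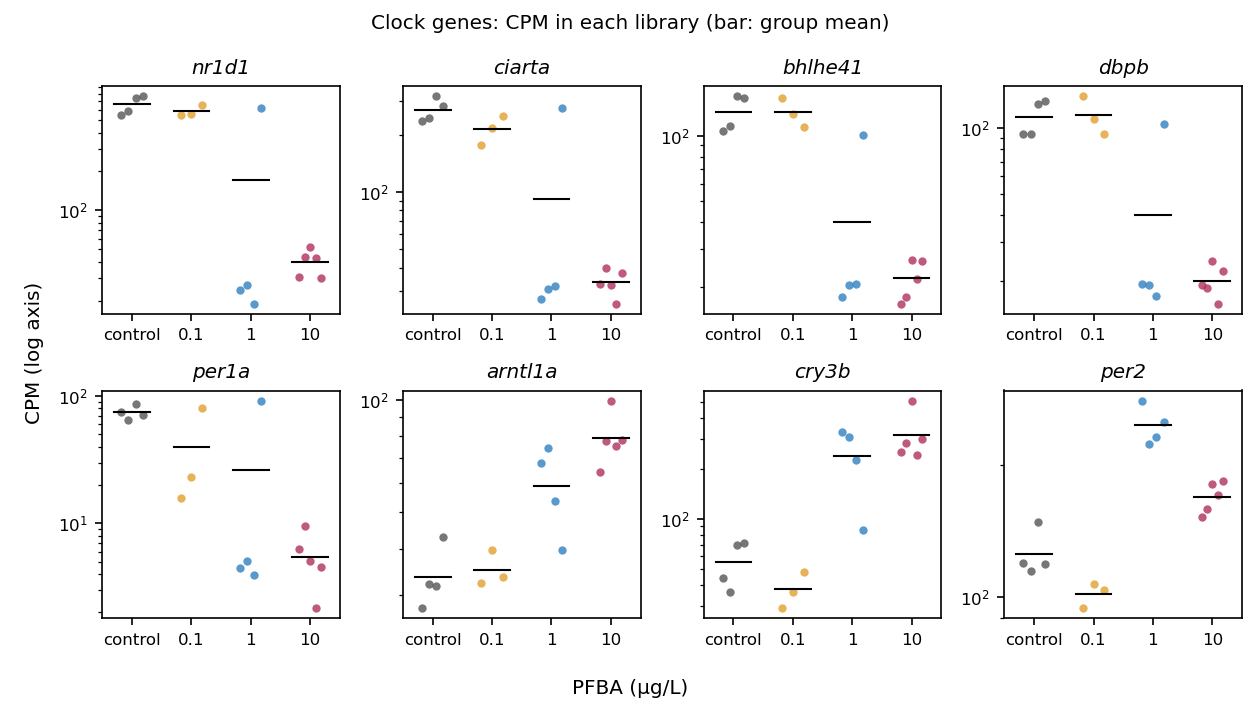
CPM of 7 genes of the fixed clock list and of cry3b in each library on a log axis, by PFBA dose in µg/L, with a bar at each group mean. nr1d1 lies between 547 and 762 CPM in the controls and between 29.9 and 52.3 CPM at 10 µg/L, while library 5 at 1 µg/L lies at 617 CPM.

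**Figure D3:**
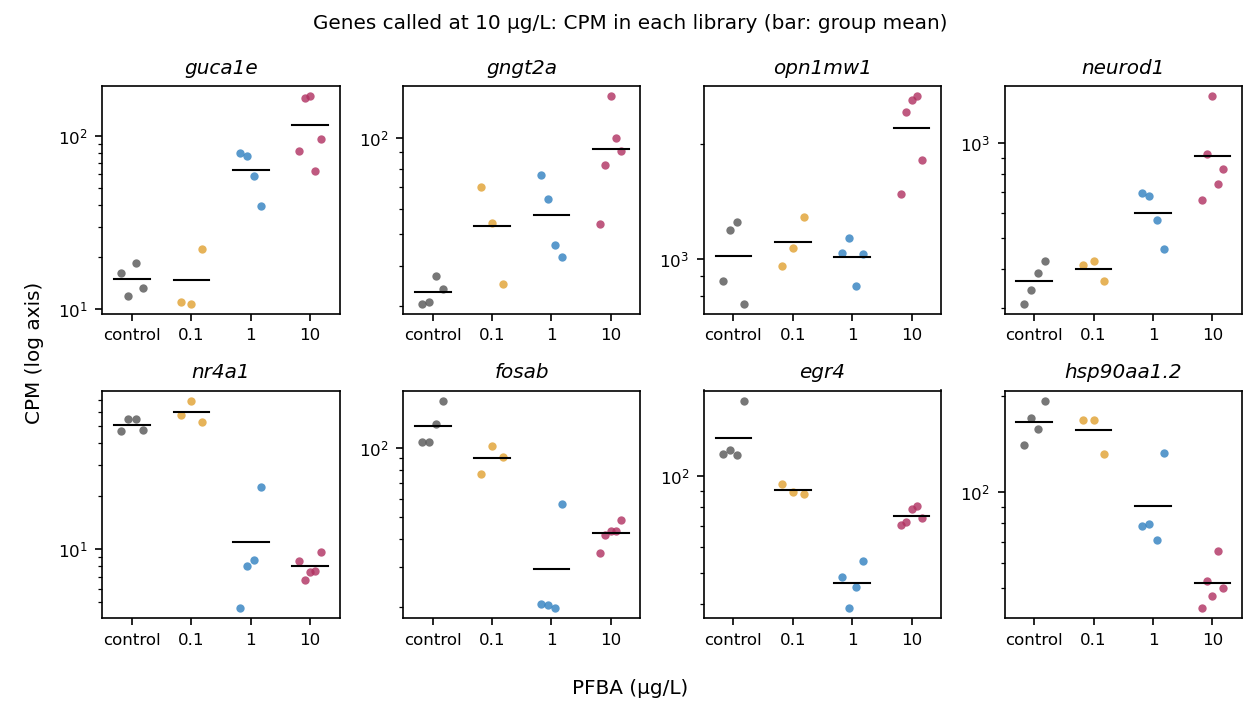
CPM of 8 genes called at 10 µg/L in each library on a log axis, by PFBA dose in µg/L, with a bar at each group mean. guca1e lies at most at 18.6 CPM in the controls and at least at 62.4 CPM at 10 µg/L, and hsp90aa1.2 at least at 141 CPM in the controls and at most at 65.2 CPM at 10 µg/L.

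Among the fixed lists, 16 of 44 were called at 10 µg/L with the preset correlation, 5 higher and 11 lower (limma camera, Benjamini-Hochberg), 0 were called with an estimated correlation, and fry called 1, inflammation and interferon (adjusted p = 0.0496). Of 29 measured clock genes 3 rose and 5 fell, or 5 rose and 14 fell adjusted over the list alone, and 21 did not pass over all genes. Their median log2 fold change was -0.67, and the adjusted p was 6.39e-05 with the preset and 0.496 with an estimated correlation (limma camera). The lens list had the largest median, 0.82 over 31 members, of which 0 passed over all genes and 15 rose adjusted over the list alone (limma camera adjusted p = 1.56e-16, adjusted p = 0.443 with an estimated correlation). Its crystallin genes crygm2d3 and cryba1l1 were 1.45 and 1.15 higher on the log2 scale without passing (edgeR adjusted p = 0.205 and 0.21). Of the 35 photoreceptor genes 14 rose and 5 fell adjusted over the list alone (median 0.34, adjusted p = 0.496 with an estimated correlation). The retinal pigment epithelium and retinoid cycle list had a median of 0.41 over 15 members, 0 of which passed over all genes and 2 of which rose adjusted over the list alone (adjusted p = 0.443 with an estimated correlation).

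Of 23 intestine markers 0 passed at 10 µg/L over all genes and 7 fell adjusted over the list alone, with a median of -0.72 (adjusted p = 0.496 with an estimated correlation). The lactase gene lct had a log2 fold change of -3.07 and the meprin gene mep1a.1 of -1.60 (edgeR adjusted p = 0.0837 and 0.143). Of 21 inflammation and interferon genes 6 fell adjusted over the list alone, with 0 over all genes and a median of -0.35 (adjusted p = 0.443 with an estimated correlation). socs3a, a feedback inhibitor of cytokine signalling, was at -1.19 and nfkbiab, which encodes an inhibitor of NF-kappa-B, at -1.01 on the log2 scale (edgeR adjusted p = 0.0721 and 0.131). Of 12 glucocorticoid and stress axis genes 4 fell adjusted over the list alone, with 0 over all genes and a median of -0.42 (adjusted p = 0.496 with an estimated correlation), and per1a, which is also a clock gene, and fkbp5 were at -3.76 and -2.42. Of 27 heat shock genes 1 fell, hsp90aa1.2, and the median was -0.26 (adjusted p = 0.496 with an estimated correlation). Xenobiotic metabolism, lipid transport and storage, complement and acute phase, skeletal muscle, heart and liver were also lower, with medians of -0.29, -0.51, -0.49, -0.48, -0.51 and -0.32, and cell cycle and oxidative phosphorylation higher, at 0.12 and 0.06. None of their members passed over all genes, and their adjusted p with an estimated correlation was between 0.496 and 0.772.

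Library 3 at 10 µg/L moved with the trunk lists: without it the calls of liver, skeletal muscle, complement, lipid transport and heart ended (limma camera adjusted p = 0.915, 0.371, 0.133, 0.0975 and 0.0975). Without control library 1 those of liver, skeletal muscle, heart and complement ended (0.496, 0.121, 0.124 and 0.0538), without control library 3 those of liver, skeletal muscle, heart and lipid transport (0.35, 0.299, 0.0545 and 0.0545), and without library 2 at 10 µg/L that of liver (0.146). The calls of oxidative phosphorylation and cell cycle ended without control library 5, with the direction turned (0.922 for both), and without library 4 at 10 µg/L (0.609 and 0.28), and that of the glucocorticoid list without control library 5 (0.0848).

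The comparison of 1 µg/L with control gave a smaller set, with egr4, fosab, nr4a1 and npas4a among the lower genes and per2, cry3b and guca1e higher. egr4, an early growth response gene, fell from 131 ± 26.7 to 46.7 ± 6.42 CPM (SD, n = 4 and 4; edgeR adjusted p = 0.000263). fosab fell 4.26-fold, nr4a1 4.62-fold, and npas4a, an activity-dependent transcription factor gene, 4.20-fold, with edgeR adjusted p-values of 0.00561, 0.0126 and 0.0292. per2, a clock gene induced by light, rose from 126 ± 15.5 to 246 ± 24.9 CPM (SD, n = 4 and 4; log2 fold change 0.97, SE 0.13, edgeR adjusted p = 0.00528). cry3b rose 4.28-fold and guca1e 4.24-fold (edgeR adjusted p = 0.0379 and 0.0274).

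Also lower at 1 µg/L were the COPII coat gene sec23b (2.59-fold), the antiproliferation gene btg2 (2.89-fold), the ammonium transporter gene rhcga (3.35-fold), the transcription factor gene klf2a (3.34-fold), the matricellular gene ccn1 (2.49-fold) and the ERK phosphatase gene dusp6 (1.83-fold). In all, 13 genes passed, 3 higher and 10 lower (edgeR, Benjamini-Hochberg), of 934 at an unadjusted p below 0.05. In each of the 13 the 4 exposed libraries lay on the same side of the control mean, which the choice of genes by their p-value favours. The fit of these 2 groups alone called 6, DESeq2 70 and limma-voom 151, and the authors' deposited table had 112 genes with an adjusted p below 0.05, 42 higher and 70 lower.

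Library 5 at 1 µg/L stood apart in clock genes: nr1d1 was at 617 CPM in it and at 19 to 26.5 CPM in the other 3, and per1a at 91.7 against 3.90 to 5.10 CPM. Without it 105 genes were called at 1 µg/L. The count was 6, 5, 5 and 8 without control library 1, 3, 4 or 5, 6, 5 and 5 without library 1, 2 or 4 at 1 µg/L, and 7 and 8 without library 2 or 5 at 10 µg/L. egr4 and sec23b kept their call in all 26 alternatives, and fosab, btg2 and per2 kept it in every fit with 1 library left out. The edgeR fit of these groups alone ended the calls of fosab (adjusted p = 0.207), btg2 (0.057), nr4a1 (0.216), npas4a (0.327), cry3b (0.31), ccn1 (0.057) and dusp6 (0.138). Library size only ended those of per2, cry3b, guca1e and dusp6 (edgeR adjusted p = 0.228 for each), npas4a (0.141), rhcga (0.186) and ccn1 (0.0595). klf2a also lost it with DESeq2 size factors in edgeR (0.0628), cry3b, klf2a and dusp6 without a filter on low counts (0.0524, 0.0545 and 0.054), and klf2a, ccn1 and dusp6 with the length trend removed (0.123, 0.123 and 0.256), and cry3b and npas4a without libraries 1 and 2 at 0.1 µg/L (0.104 and 0.0749). nr4a1 also lost it without control library 3 (0.052) or 4 (0.0553) or library 2 (0.108) or 4 (0.0865) at 1 µg/L. Of the 16 fits with 1 library left out, cry3b lost its call in 14, klf2a and dusp6 in 13, npas4a and ccn1 in 9, rhcga in 8 and guca1e in 7. The highest edgeR adjusted p was 0.266 for cry3b without control library 1, 0.273 for klf2a without library 4 at 1 µg/L, and 0.256, 0.204, 0.209, 0.209 and 0.134 for dusp6, npas4a, ccn1, rhcga and guca1e without library 1 at 1 µg/L. With library size only 6 genes were called, 0 higher and 6 lower.

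At 1 µg/L 14 lists were called, 8 higher and 6 lower (limma camera), 0 with an estimated correlation and 0 by fry. Of 29 clock genes 1 rose, per2, and 6 rose and 8 fell adjusted over the list alone, with a median of -0.31 (adjusted p = 0.946 with an estimated correlation). Of 23 intestine markers 2 fell adjusted over the list alone, with a median of -0.70, and lct was at -2.63 without passing (edgeR adjusted p = 0.537). Of 21 inflammation and interferon genes 3 fell adjusted over the list alone, with a median of -0.35, and socs3a was at -1.37 without passing (edgeR adjusted p = 0.14). The adjusted p with an estimated correlation was 0.946 for intestine and 0.462 for inflammation. Glucocorticoid and stress axis, xenobiotic metabolism, and lipid transport and storage had lower medians of -0.48, -0.29 and -0.45. Proteasome, lens, exocrine pancreas, Nrf2 and oxidative stress, ribosomal proteins, oxidative phosphorylation, glycolysis and skeletal muscle had higher medians of 0.35, 0.36, 0.37, 0.27, 0.23, 0.19, 0.18 and 0.11. None of the members of these 11 lists passed over all genes or adjusted over the list alone, and the adjusted p of each was 0.946 with an estimated correlation. Of the 16 fits with 1 library left out, 8 ended the call of skeletal muscle, with limma camera adjusted p-values from 0.0578 to 0.745: those without control library 4 or 5, without any of the 3 libraries at 0.1 µg/L, without library 2 or 4 at 1 µg/L and without library 4 at 10 µg/L, and its direction turned without control library 5 (0.31). Lipid transport lost its call without control library 1 (0.161) or 3 (0.235) or library 1 (0.114) or 5 (0.0512) at 1 µg/L. Glycolysis lost it without control library 5 (0.719) or library 1 (0.0658), 2 (0.089) or 4 (0.142) at 1 µg/L. The clock lost it without control library 4 (0.0614) or 5 (0.0547) or library 2 at 1 µg/L (0.265), and xenobiotic metabolism without control library 3 (0.0729) or library 5 at 1 µg/L (0.0579). Oxidative phosphorylation and exocrine pancreas lost it without control library 5 (0.102 and 0.104), and the glucocorticoid list without library 2 at 1 µg/L (0.097).

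The overlap between the doses asked which genes changed in both. 7 genes were called in the same direction at 1 and 10 µg/L: cry3b and guca1e were higher, and nr4a1, fosab, egr4, btg2 and ccn1 lower. Independent lists of these sizes would share 0.00251 higher and 0.0141 lower genes. In 20 simulations of unchanged groups against the same controls the overlap was at most 0. Unchanged groups yield few called genes, so this value says little about the effect of shared controls. Across genes, which are not independent replicates, the log2 fold changes at 1 and 10 µg/L had a Pearson correlation of 0.65, against 0.52 (0.51 to 0.54) for simulated unchanged groups, and a covariance of 0.138 against 0.102. With the 4 controls split between the comparisons the correlation had a median of 0.23 over 6 splits (-0.02 to 0.32) and the calls in common were 0. Each comparison then had fewer controls and its own calls were not counted, so this 0 does not tell whether the overlap rests on shared controls. At 0.1 µg/L, with 0 called genes, the overlap with either dose was 0, and the correlation with 1 and 10 µg/L was 0.27 and 0.13, against 0.45 and 0.47 in the simulations, with covariances of 0.085 and 0.045 against 0.1. All these simulations drew genes independently and gave each gene the same spread in all groups. That spread was estimated with the libraries at 0.1 µg/L, of which libraries 1 and 2 stood apart. The simulated values therefore do not decide how much of a correlation or covariance comes from shared controls. The overlap was 3, 0, 1 and 2 genes without control library 1, 3, 4 or 5, 4 without library 2 at 0.1 µg/L, 4, 3, 2 and 76 without library 1, 2, 4 or 5 at 1 µg/L, and 2 and 3 without library 2 or 5 at 10 µg/L. At 10 µg/L the calls of btg2, egr4 and ccn1 ended in 11, 4 and 3 of the 16 fits with 1 library left out, with edgeR adjusted p-values up to 0.141 and 0.0724 without library 2 at 10 µg/L and 0.0624 without control library 1. Library size only and the removal of the length trend also ended those of egr4 (0.0948 and 0.0989) and btg2 (0.0646 and 0.13) at 10 µg/L.

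At 0.1 µg/L the comparison with control called 0 genes (edgeR), with 4157 genes at an unadjusted p below 0.05 and a smallest adjusted p of 0.0858. DESeq2 called 1432 genes, 1224 higher and 208 lower, and limma-voom with quality weights 8718, 3732 higher and 4986 lower, and the authors' deposited table had 70 genes with an adjusted p below 0.05, 68 higher and 2 lower. The genes with the lowest p were atp5meb, a subunit gene of ATP synthase, at 37.7 ± 6.38 CPM in controls and 75.7 ± 19.7 CPM in the exposed (SD, n = 4 and 3), the lens crystallin gene cryba4 with a log2 fold change of 1.85, the complex I gene ndufa6 at 1.78, CABZ01078055.1 at 1.63 and the deubiquitinase gene usp20 at -1.47, all with an edgeR adjusted p of 0.0858. In each of these 5 genes all 3 exposed libraries lay on the same side of the control mean. Without library 3 at 0.1 µg/L, 6256 genes were called, 2466 higher and 3790 lower.

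The fixed lists moved widely at 0.1 µg/L without a called gene: 25 were called, 23 higher and 2 lower (limma camera), 0 with an estimated correlation and 0 by fry. Of 72 ribosomal protein genes 69 were higher adjusted over the list alone, with a median of 1.32, and libraries 1 and 2 held rps3a at 364 and 241 CPM against 92.9 in library 3 and 71.2 to 93.4 in controls. Of 33 proteasome genes 32 were higher adjusted over the list alone (median 1.25), of 40 oxidative phosphorylation genes 33 (median 1.01), of 36 skeletal muscle markers 25 (median 1.48), of 31 lens genes 23 (median 1.31) and of 21 exocrine pancreas markers 13 (median 1.44). Intestine, liver, epidermis, and lipid transport and storage had medians of 1.1, 1.25, 1.03 and 1.01, and heart and complement of 0.79 and 0.70. The remaining higher lists, glycolysis, cartilage and bone, heat shock, fatty acid oxidation, Nrf2 and oxidative stress, erythroid, amino acid catabolism, extracellular matrix, pigment cell, mitochondrially encoded and xenobiotic metabolism, had medians from 0.22 to 0.52. The lower lists were the nuclear receptors with PPAR and RXR (median -0.61) and the clock (median -0.33), in which 1 and 0 genes fell adjusted over the list alone. The adjusted p with an estimated correlation was 0.338 to 0.565 for these 25 lists (limma camera). Of the 16 fits with 1 library left out, 4 ended the call of the mitochondrially encoded list, those without control library 1 (0.311) or 3 (0.072) or library 1 (0.123) or 2 (0.114) at 0.1 µg/L. Without control library 5 the calls of extracellular matrix, pigment cell, amino acid catabolism, cartilage and bone, and erythroid ended (0.0762, 0.0696, 0.0577, 0.0544 and a value that rounds to 0.05). Extracellular matrix and pigment cell also lost it without library 3 at 0.1 µg/L (0.0552 and 0.0654), heat shock without library 1 (0.0841) and the nuclear receptors without library 2 (0.0574, limma camera adjusted p throughout). Over the 23 higher lists the median of the list medians was 0.70 with all 3 libraries and 0.22 in library 3 alone. Without libraries 1 and 2, where library 3 is assumed to vary like the other groups, 10 lists were called, 9 higher and 1 lower, and the ribosomal proteins, now lower, were 1 of them (limma camera adjusted p = 0.0137). With library size only the median of all genes shifted by -0.42 on the log2 scale at 0.1 µg/L, so these changes are relative to that shift.

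**Figure D4:**
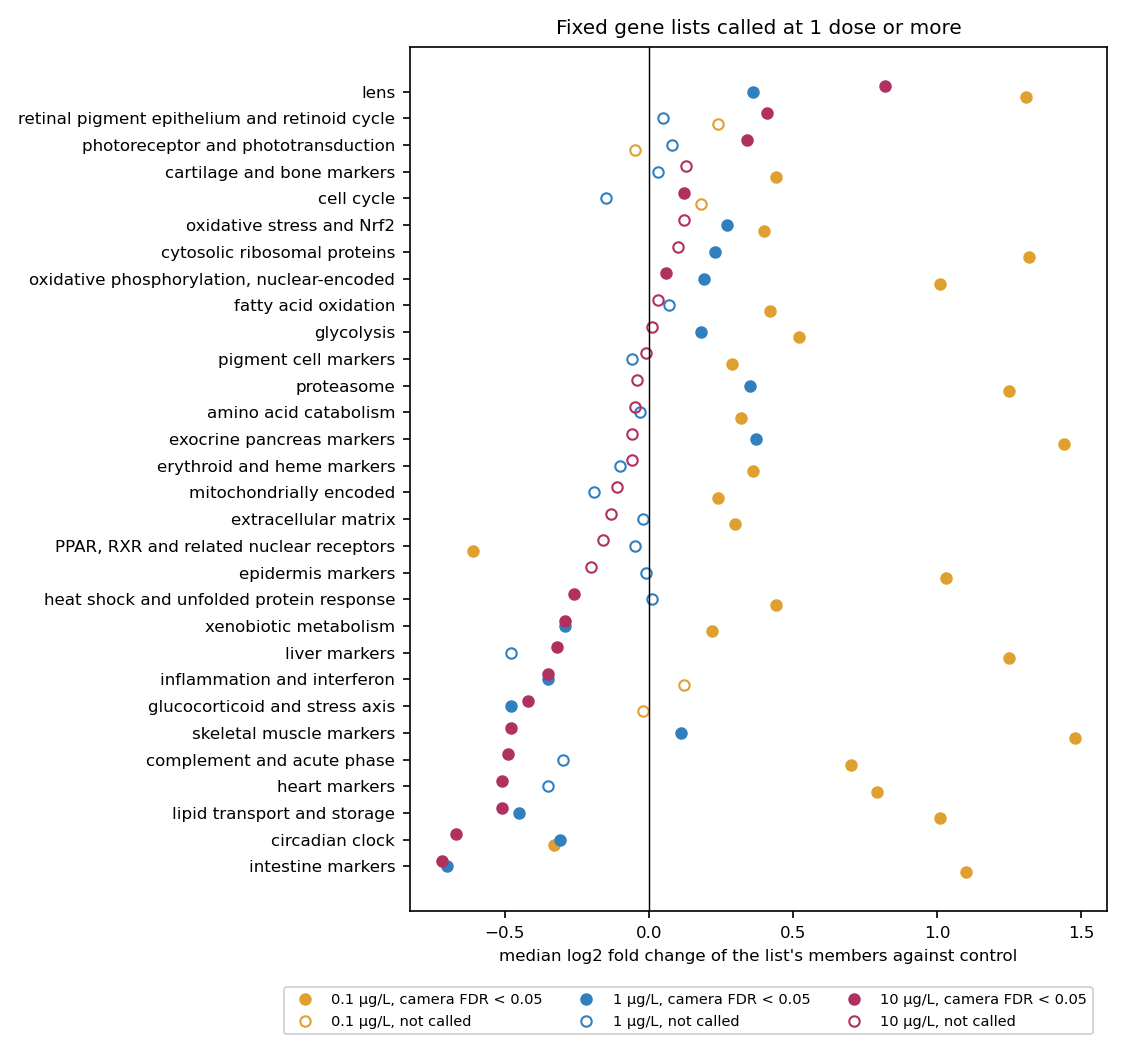
Median log2 fold change against control of the members of each fixed list called at 1 dose or more, with filled points where the list was called by limma camera with a preset correlation of 0.01 and open points where it was not. The lens list lies at 1.31, 0.36 and 0.82 at 0.1, 1 and 10 µg/L and the intestine list at 1.1, -0.70 and -0.72.

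The dose trend asked which genes had a slope over equal dose steps from control to 10 µg/L. CABZ01117503.1, annotated as similar to the inhibin beta B chain, had the lowest p. Its means were 0.0539, 0.0574, 1.05 and 5.26 CPM in the 4 groups (edgeR adjusted p = 0.00013). guca1e rose by 1.05 on the log2 scale per step (SE 0.12), arntl1a by 0.44, neurod1 by 0.45 and rorcb by 0.87, with edgeR adjusted p-values of 0.000699, 0.00532, 0.00643 and 0.00747. hsp90aa1.2 had a slope of -0.59 (SE 0.07), nr4a1 of -1.05, CR926130.2 of -1.07, itpkcb of -0.66 and bhlhe41 of -0.95, with edgeR adjusted p-values of 0.000699, 0.00532, 0.00532, 0.00556 and 0.00826. Each of these 10 named genes kept its call in every fit with 1 library left out. A slope does not show a change at each step, and 0 genes were called between 10 and 1 µg/L (edgeR). At 1 µg/L bhlhe41 was at 100 CPM in library 5 and at 18 to 20.7 CPM in the others. In all, 55 genes passed, 21 higher and 34 lower (edgeR), of 1924 at an unadjusted p below 0.05. Of the lists 16 had a trend, 3 higher and 13 lower (limma camera), 0 with an estimated correlation, with fry calling inflammation and interferon (adjusted p = 0.0377). The adjusted p of the 16 was between 0.350 and 0.830 with an estimated correlation (limma camera). The steepest were intestine (median -0.42 per step), skeletal muscle (-0.37), lipid transport (-0.31), liver and heart (-0.29 each), complement (-0.25) and the clock (-0.20). All of these but the clock were higher than control at 0.1 µg/L, with medians of 1.1, 1.48, 1.01, 1.25, 0.79 and 0.70. Their slopes thus do not describe a fall from control at each step. Lens, photoreceptor and retinal pigment epithelium lists had slopes of 0.14, 0.12 and 0.12. Ribosomal proteins (-0.12), epidermis (-0.18), heat shock (-0.17), glucocorticoid (-0.16), inflammation (-0.15) and xenobiotic metabolism (-0.14) also had negative slopes. Ribosomal proteins, epidermis, heat shock and xenobiotic metabolism were likewise higher than control at 0.1 µg/L, with medians of 1.32, 1.03, 0.44 and 0.22. The ribosomal call ended in 6 of the 16 fits with 1 library left out, those without library 1 (limma camera adjusted p = 0.941) or 2 (0.463) at 0.1 µg/L and library 1 (0.142), 2 (0.455), 3 (0.315) or 5 (0.13) at 10 µg/L, and without both libraries 1 and 2 at 0.1 µg/L its trend turned higher and was called (0.000787). The epidermis call ended without library 3 at 10 µg/L (0.0928) and without libraries 1 and 2 at 0.1 µg/L (0.142).

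The trend count was 35, 35 and 27 without control library 1, 3 or 4, 97 without library 1 at 0.1 µg/L, 85 without library 5 at 1 µg/L, 23, 27, 27 and 33 without library 2, 3, 4 or 5 at 10 µg/L (15 higher and 12 lower without library 4), and 178 without libraries 1 and 2 at 0.1 µg/L. With library size only, 12 genes rose and 35 fell.

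Comparing the doses with each other, edgeR called 37 genes between 1 and 0.1 µg/L, 11 higher and 26 lower at 1 µg/L, and 2025 between 10 and 0.1 µg/L, 623 higher and 1402 lower at 10 µg/L. With library size only these splits were 2 and 0, and 926 and 269. Between 10 and 1 µg/L 0 genes were called (edgeR), with 550 at an unadjusted p below 0.05, 11 by DESeq2 and 0 by limma-voom. Without libraries 1 and 2 at 0.1 µg/L the count was 0 in each of these comparisons. The 1 against 0.1 µg/L count was 4, 9 and 6096 without library 1, 2 or 3 at 0.1 µg/L, 3, 2, 17 and 172 without library 1, 2, 4 or 5 at 1 µg/L, and 21, 23, 60, 67 and 15 without library 1, 2, 3, 4 or 5 at 10 µg/L. The 10 against 0.1 µg/L count was 86, 261 and 7151 without library 1, 2 or 3 at 0.1 µg/L, and 611, 1222 and 1044 without library 2, 3 or 5 at 10 µg/L. Without library 5 at 1 µg/L 1 gene was called between 10 and 1 µg/L.

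The F test over the 4 groups called 447 genes (edgeR), of 3920 at an unadjusted p below 0.05, and guca1e, nr4a1, egr4, per2 and hsp90aa1.2 all had its smallest adjusted p of 0.000691. The count was 160, 205, 152 and 235 without control library 1, 3, 4 or 5, 71, 58 and 5349 without library 1, 2 or 3 at 0.1 µg/L, 178 and 193 without library 1 or 2 at 1 µg/L, and 182, 77, 183, 820 and 123 without library 1, 2, 3, 4 or 5 at 10 µg/L. Without libraries 1 and 2 at 0.1 µg/L it was 36.

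Sentinel genes of lipid sensing, xenobiotic and oxidative stress responses, fixed before the data were examined, are given as values. At 10 µg/L the log2 fold changes were -0.15 for the fatty acid sensor gene pparaa, -0.44 for pparab, 0.05 for the carnitine palmitoyltransferase gene cpt1aa, -0.89 for the dioxin-responsive gene cyp1a, 0.41 for catalase (cat), 0.31 for sod1 and 0.65 for hmox1a. None of these 7 passed at any dose (edgeR), with adjusted p-values at 10 µg/L of 0.312 or higher. Further, 14 of the 44 lists were called in no comparison: leukocyte, neurotransmission, bile acid, mitochondrial biogenesis, neuron, thyroid, estrogen and steroidogenesis, p53, glia, fatty acid synthesis, insulin and glucagon, organic anion transport, cholesterol synthesis, and kidney and ionocyte. Their medians lay between -0.41 and 0.34 on the log2 scale and their smallest limma camera adjusted p was 0.0627. Median, mean and test differed in sign in 31 of the 176 list results, and 0 of these were called.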

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

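The tests chosen only after their results were seen are those of the time of collection, of a wrong label on library 5 at 1 µg/L (both tests), of PFBA acting on the clock, of exposure as the cause of the 0.1 µg/L pattern, and all counts over other splits. The tests of gene length and of a few abundant genes were written before their own results, but after the 0.1 µg/L pattern was seen.

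Library 5 at 1 µg/L stood far from the other 3 libraries of its group, by Dixon's ratio on log2 CPM, in 14 genes, and these were all the single-library departures at that dose. It was higher in nr1d1 (617 CPM against 19 to 26.5), ciarta (276 against 27.4 to 32), bhlhe41 (100 against 18 to 20.7), dbpb (104 against 17 to 19.3), per1a (91.7 against 3.9 to 5.1), fkbp5 (438 against 16.6 to 23.6) and nfkbiab (168 against 65 to 66.7). It was also higher in fosab (56.6 against 19.8 to 20.6), npas4a (155 against 43.9 to 50.6), btg2 (123 against 60.4 to 67) and ccn1 (18.4 against 12.2 to 13). It was lower in cry5 (18 against 24.6 to 26.2), nfil3-5 (7.94 against 14.6 to 16) and opn1lw2 (554 against 943 to 1010). Over all named genes and library measures 26 of 318 groups held such a library, where chance gives about 1 in 20, or 15.9.

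The clock pattern at 1 and 10 µg/L has 2 candidate explanations, the time of collection and PFBA, and a wrong label could account only for the departure of library 5 at 1 µg/L; the tables exclude none of the 3. Collection at another time of day would move the clock's arms in opposite directions. Of 29 clock genes 6 lay above all controls in all 5 libraries at 10 µg/L and 14 below, against 0.79% per direction by chance. That chance holds for a single gene, while clock genes vary together, and the share over all tested genes is not given here. A PFBA effect on the clock could also move its arms in opposite directions, and collection times are not given in the sources used here. A wrong label, with library 5 at 1 µg/L being a control, stays open: it lay beyond all controls in 41% of the 105 genes called at 1 µg/L without it, against 15% to 45.9% for each control left out and set against the other 3, and in 42% of the 157 genes called at 10 µg/L in the fit of those groups alone, which is above each left-out control (19.4% to 39.8%) and below the other 3 libraries at 1 µg/L (94.3% to 98.7%). A left-out control had 3 others to pass, not 4, and its own list of genes, so these shares are not directly comparable. Library 5 also lay beyond all controls in each of the 13 genes called at 1 µg/L. In per2 it was at 251 CPM against at most 149. Library 5 entered the fit that chose these genes, so this does not decide on a wrong label. The test of PFBA acting on the clock asked, after the result was seen, for 3 of 4 libraries at 1 µg/L to move. In 3 of them 15 of 15 called clock genes lay beyond the controls, against 4 of 15 in library 5. Libraries 1, 2 and 3 at 0.1 µg/L held 10, 9 and 2 of 15. These genes were called against the same controls, which favours such counts. In the other 142 called genes these 3 libraries at 1 µg/L lay beyond the controls in 93.7% to 98.6%. The counts are thus not particular to the clock and do not decide on PFBA.

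At 0.1 µg/L 23 lists were higher with the preset correlation (limma camera; 0 with an estimated correlation, adjusted p from 0.338 to 0.565 over the 25 called lists), and libraries 1 and 2 went with part of this. Without them only library 3 is left, so no spread within this dose could be measured. In library 3 the mean log2 CPM of the intestine list relative to all libraries was 1.17, against -0.38 to 0.74 in controls. The lens list was at -0.05 in library 3, against -0.72 to -0.16 in controls. The ribosomal proteins went from a median of 1.32 with all 3 libraries to -0.08 in library 3 alone. Gene length bias was excluded as the whole cause: the list medians kept a median of 125.8% with the length trend removed. Without the 50 most abundant genes the list medians kept a median of 116.6%. TMM scaling already limits the weight of such genes in the main fit. This value therefore does not decide on a few genes taking most of the counts. Exposure to 0.1 µg/L stays open: library 3 alone kept a median of 28.2% (quartiles 9.3% and 75.8% over the lists), and with 3 libraries a true difference between them cannot be told apart from a difference in preparation. No batch is given in the sources used here.

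Other splits of the same libraries tested whether chance can be excluded. Without adjustment for the number of such tests, chance was unlikely for the genes called at 1 and 10 µg/L and in the dose trend. At 1 µg/L 1 of 35 splits gave as many, the real one (real 13, highest other 0), which is the smallest share possible. At 10 µg/L it was 1 of 100 (43 and 2), in the F test 2 of 100 (447 and 855) and in the dose trend 1 of 100 (55 and 0). The F test count was 36 without libraries 1 and 2 at 0.1 µg/L. Its low share of splits therefore cannot be told apart from the departure of these libraries. Chance was not excluded for genes between 1 and 0.1 µg/L (5 of 35, 37 and 2601) and between 10 and 0.1 µg/L (3 of 56, 2025 and 4411). With a real count of 0, every split must give as many, so this test says nothing of genes at 0.1 µg/L (35 of 35; 0 and 1082) or between 10 and 1 µg/L (100 of 100; 0 and 1). For the lists it was not excluded at 0.1 µg/L (11 of 35; 25 and 28), at 1 µg/L (20 of 35; 14 and 29), at 10 µg/L (59 of 100; 16 and 29) or for the trend (51 of 100; 16 and 29). The splits with 2601 and 4411 genes kept libraries 1 and 2 at 0.1 µg/L together, which points to a structure of these samples.

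The remaining single-library values and differences between doses are given without explanation. In controls, acadm was at 113 CPM in library 1 against 131 to 135 in the others, and library 5 held egr4 at 171 against 116 to 121, dusp6 at 95 against 68.2 to 71.7 and cdc20 at 3.21 against 5.81 to 6.53. At 10 µg/L, library 4 held CABZ01078055.1 at 17.6 CPM against 8.4 to 9.94, psma1 at 191 against 117 to 127, gpr143 at 8.19 against 5.8 to 6.3 and sod1 at 101 against 58.5 to 68.4. Also at 10 µg/L, usp20 was at 20.6 CPM in library 5 against 12 to 14.1, cpt1aa at 56.2 in library 3 against 36.4 to 39.7, itpkcb at 6 in library 3 against 8.91 to 9.54, and cry5 at 8.06 in library 2 against 13 to 15.6. The test of the difference between doses called 37 genes between 1 and 0.1 µg/L and 2025 between 10 and 0.1 µg/L (edgeR), against 4 and 86 without library 1 at 0.1 µg/L, 9 and 261 without library 2, 6096 and 7151 without library 3, and 0 and 0 without libraries 1 and 2.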

How the results depend on the processing

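The block for the number in the column name, the fits without libraries 1 and 2 at 0.1 µg/L (with or without library 5 at 1 µg/L), the removal of a length trend and the alternatives for the overlap were chosen after seeing the data. Over all alternatives 49 called values of named genes were the same in 1006 of 1272 cases, lost their call in 266 and reversed in 0; 90 values without a call were the same in 2093 of 2338, gained one in 221 and reversed in 24. Where a count moved, the cause was not tested, unless fewer libraries or groups entered the fit.

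With DESeq2 size factors in edgeR 86 genes were called between 1 and 0.1 µg/L. With library size only the counts were 6 at 1 µg/L, 51 in the F test, 2 between 1 and 0.1 µg/L, 1195 between 10 and 0.1 µg/L and 3 in the overlap; cyp1a and cat at 0.1 µg/L turned to -0.23 and -0.29 and pparaa at 1 µg/L to -0.02 on the log2 scale. DESeq2 called 1432, 70 and 259 genes at 0.1, 1 and 10 µg/L, 2403 in the F test, 459 in the trend, 1496 between 1 and 0.1 µg/L, 3478 between 10 and 0.1 µg/L, 11 between 10 and 1 µg/L and 53 in the overlap. It gave no adjusted p for nr1d1, ciarta, per1a and fkbp5 at 10 µg/L. Limma-voom with quality weights called 8718, 151 and 323 genes at the 3 doses, 9429 in the F test, 530 in the trend, 9241 between 1 and 0.1 µg/L, 10551 between 10 and 0.1 µg/L and 104 in the overlap, with cyp1a at 0.1 µg/L at -0.17 and cpt1aa at 1 µg/L at 0.02.

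Libraries share only a number across groups: the deviations of 18 pairs with the same number had correlations from -0.44 to 0.45 (median -0.10), and those of 77 pairs with other numbers from -0.50 to 0.46 (median 0.01). With the replicate block by the number in the column name 6 and 8 genes were called at 1 and 10 µg/L, 53 in the F test, 16 in the trend, 18 between 1 and 0.1 µg/L, 544 between 10 and 0.1 µg/L and 2 in the overlap, and cpt1aa at 1 µg/L was at 0.01. This block ended the calls of cry3b, guca1e, per2, rhcga, klf2a, ccn1 and dusp6 at 1 µg/L (edgeR adjusted p from 0.0539 to 0.277) and of rorcb in the trend (0.0612). At 10 µg/L it ended those of cry3b, rorcb, fbxl3l, nfil3-5, aanat2, gngt2a, neurod1, ptpdc1b, arntl1a, nr1d1, ciarta, fosl1a, dbpb, CABZ01051602.1, gpr186, opn1mw1, egr4, btg2 and ccn1 (0.0506 to 0.202). In fits of only the groups compared 6 and 157 genes were called at 1 and 10 µg/L, 0 between 1 and 0.1 µg/L, 154 between 10 and 0.1 µg/L (17 higher and 137 lower) and 4 in the overlap. The slope over the exposed groups alone called 679 genes, 95 higher and 584 lower. With an estimated correlation 0 lists were called in any comparison, and with fry 0, 0 and 1 at the 3 doses and 1 in the trend. With the controls split 2 and 2 the overlap was 0.

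Without libraries 1 and 2 at 0.1 µg/L the counts were 80 at 10 µg/L, 36 in the F test, 178 in the trend and 0 between 0.1 µg/L and either other dose, with 10 lists at 0.1 µg/L. Leaving out library 5 at 1 µg/L as well gave 166 and 215 genes at 1 and 10 µg/L, 177 in the F test, 265 in the trend, 56 between 1 and 0.1 µg/L, 42 between 10 and 0.1 µg/L, 1 between 10 and 1 µg/L, 114 in the overlap and 10 lists at 0.1 µg/L. In both of these fits psma4, fabp6, apoea and pparab at 0.1 µg/L were at 0.00, -0.38, -0.10 and 0.60. With the length trend removed 368 genes were called at 0.1 µg/L, 707 in the F test and 111 between 1 and 0.1 µg/L; the trend called 22 higher and 15 lower, and cpt1aa at 1 µg/L was at 0.02.

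Leaving out 1 library at a time gave 0 to 6256, 5 to 105 and 10 to 131 genes at 0.1, 1 and 10 µg/L, 58 to 5349 in the F test, 23 to 97 in the trend, 2 to 6096 between 1 and 0.1 µg/L, 86 to 7151 between 10 and 0.1 µg/L, 0 to 1 between 10 and 1 µg/L and 0 to 76 in the overlap. The lists numbered 20 to 27, 10 to 14 and 14 to 20 at the 3 doses and 14 to 22 in the trend. Sentinel genes near 0 turned sign: at 10 µg/L cpt1aa was at -0.02 without control library 1 and at -0.08 without library 3 at 10 µg/L. At 1 µg/L pparaa was at -0.02 without control library 3, control library 4 or library 1 at 1 µg/L, pparab at -0.07 without control library 4, and cpt1aa at 0.06 without control library 5 and 0.03 without library 4 at 1 µg/L. At 0.1 µg/L cyp1a was at -0.06 without control library 5. The highest or lowest values on the other side were 0.15 for cpt1aa at 10 µg/L without control library 5, 0.13 for pparaa and -0.11 for cpt1aa at 1 µg/L without control library 1, 0.28 for pparab at 1 µg/L without library 2 at that dose, and 0.35 for cyp1a at 0.1 µg/L without control library 3. At the replicate numbers and depth of these libraries, the simulated 1.5-fold changes at 10 µg/L, set in more abundant genes, were recovered in 0% and the 4-fold ones in 80.3%. Other replicate numbers and depths were not simulated.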

Other observations

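The test on the eye lists was chosen only after the result was seen, and that on the intestine list was written before its own result was seen.

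At 10 µg/L the lens and photoreceptor lists were higher while the intestine, liver and muscle lists were lower (limma camera with the preset correlation). With an estimated correlation none of these 5 was called (adjusted p from 0.443 to 0.772), and the liver and muscle calls ended without library 3 at 10 µg/L (0.915 and 0.371). A smaller share of trunk tissue might raise the markers of the other head tissues alike. Neuron and glia markers had a mean log2 fold change of 0.02 over 41 genes, against 0.57 over 66 photoreceptor and lens genes. The difference of -0.55 (SE 0.09) has an SE over genes that vary together, not over samples. By library, the mean log2 CPM of the photoreceptor list relative to all libraries was -0.31 to 0.25 in controls and -0.26 to 0.69 at 10 µg/L. For the lens list these ranges were -0.72 to -0.16 and -0.28 to 0.62. Whether neuron and glia markers stand for head tissue alone was not tested. The difference therefore does not decide on less trunk tissue as the cause of the higher eye lists. The intestine list was -0.87 (SE 0.37) on the log2 scale at 10 µg/L and -0.67 (SE 0.20) with the mean of 4 trunk lists as a covariate. This mean measures the share of trunk tissue only in part, which can leave a difference behind. The test therefore does not exclude less trunk tissue as the whole cause of the lower intestine list. A change in the eye or the intestine itself, through exposure or through the time of collection, stays open as a hypothesis, as does less trunk tissue. Chance was not excluded for the number of lists called at 10 µg/L, since 59 of 100 splits of the same libraries gave as many.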
